A study of Mus musculus with 18 samples.

How the data were processed

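RNA was sequenced from 18 mouse brains, 3 control and 3 cKO at each of 3 stages. Per the labels' protocols, total RNA was isolated with a column kit that purifies DNA and RNA together, and stranded libraries were made after enrichment of polyadenylated RNA. Per the submitters' processing notes, FastQC, cutadapt, Trimmomatic, HISAT2, featureCounts and edgeR were used with the mouse genome build GRCm39. Their versions, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The authors deposited a table of whole-number read counts per Ensembl gene, not normalized, with 1 column per sample and 55416 genes. Each column name matched the title of 1 sample, and replicates were not pooled.

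The counts were analysed as deposited. Gene symbols came from a table of Ensembl identifiers, which named 52083 of the 55416 genes, and 40380 genes had at least 1 read in some library. Total counts per library ranged from 44030423 to 202900010, and the W8 libraries held fewer reads than those of E15 and P7. Levels are given as CPM, counts scaled to a common total by each library's total count, as mean ± SD of 3 libraries. Intervals for single libraries are 95% exact binomial (Clopper-Pearson) intervals, and a count of 0 allows up to 3 counts of the total. Both cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The chromosome order of genes was taken from an annotation of the older build GRCm38, so no coordinates are given.

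Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, estimateDisp, robust glmQLFit and glmQLFTest, with Benjamini-Hochberg adjusted p under 0.05. Control and cKO were compared within each stage from its 6 libraries. A genotype term common to the stages, with stage as a covariate, and a genotype by stage interaction (F test with 2 degrees of freedom) were fitted to all 18 libraries. Control brains were compared between P7 and E15 and between W8 and P7. Standard errors (SE) of log2 fold changes were taken as the log2 fold change divided by the square root of F. Rest was also tested by an exact two-sided permutation test of log2 CPM, whose smallest possible p with 3 against 3 is 0.1.

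The tests, the gene lists and the rule for naming genes were fixed before the data were examined. There were 44 gene lists of pathways, cell types and brain regions, 1 of them a check of sex-linked genes. The 42 lists with at least 5 measured genes at a stage were tested there with camera in limma 3.58.1 (two-sided, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01). The same test was run with a correlation estimated from the data, and fry tested whether a list's genes move, on balance, in one direction. Genes were named in this order. At each stage, up to 12 genes per direction past the threshold, with a symbol other than a predicted, RIKEN, ribosomal protein or histone gene, a mean of at least 1 CPM in some group and non-overlapping groups were taken. Where fewer than 10 passed, the 10 with the smallest p among genes meeting the symbol and CPM criteria were given as values that did not pass. Added were up to 4 members per list and direction, and genes past the threshold in several stages. For the common and interaction terms the 6 with the smallest p under the same 2 criteria were taken, and for development the 5 list members with the largest log2 fold change in each direction. Examples given for a list lie outside this rule. Between genotypes they came from the 3 members of smallest p in a list past the threshold. For development they came from called members with large log2 fold changes, so the sizes shown are selected. Markers of brain parts and of sex, and genes called only by an alternative, also lie outside it.

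Alternatives planned in advance were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 18 libraries in a shared fit, and each library left out in turn. Chosen after seeing the data were a covariate for brain-part composition, a fit of only the libraries with under 10 CPM of summed Hox genes, and 1 surrogate variable from sva 3.50.0. The covariate was the mean log2 CPM of 15 Hox genes of hindbrain and spinal cord minus that of 8 forebrain transcription factors. Other splits of the libraries were counted in all 10 ways for 3 against 3, and in 100 draws within stages for the fits of all 18 libraries.

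The main test was checked on counts simulated from the real means and library sizes, with 50 genes changed by each of 4 folds. At the 2-fold size it recovered 26% of changed genes for E15, 4% for P7, 0% for W8 and 50% for the common term, and at the 8-fold size 84%, 66%, 56% and 90%. Unchanged genes made up 10.4%, 6.15%, 0% and 6.30% of the calls in these comparisons. A shift of the microglia list by 2-fold was called at each of the 3 stages, with 0 of the other lists called. The simulated genes varied independently of each other. This check therefore cannot show how often correlation between genes leads to list calls.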

Results

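Brains of control mice and of mice with a conditional knockout (cKO) of Rest directed at the placenta were sequenced at embryonic day 15 (E15), postnatal day 7 (P7) and week 8 (W8), with 3 libraries in each of the 6 groups. REST is a zinc-finger repressor that keeps neuronal genes silent outside mature neurons. The comparison asks whether its loss in the placenta alters transcription in the brain of the fetus and, later, of the offspring. The samples are labelled as whole brain from 3 mice per group and stage. Libraries held 165413648 to 191928001 counted reads at E15 and 157963937 to 202900010 at P7. At W8 they held 44030423 to 45273844 in control and 50868250 to 60188045 in cKO brains. Reads fell on 27422 to 29627 genes at E15, 30170 to 32007 at P7 and 22653 to 24023 at W8. Replicates within a group correlated at r = 0.931 to 0.990 across genes.

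Libraries of the same group differed widely in genes that mark parts of the brain. Foxg1, a transcription factor of the forebrain, ranged from 30.2 to 378 CPM between libraries at E15, from 0.729 (interval 0.610 to 0.864) to 77.8 CPM at P7 and from 0.113 (interval 0.0367 to 0.264) to 86.1 CPM at W8. The sum of 15 Hox genes, which are expressed in hindbrain and spinal cord, ranged from 0.0483 to 392 CPM at E15, from 0.0570 to 220 CPM at P7 and from 0 (which allows up to 0.0663 CPM) to 138 CPM at W8. Under 10 CPM of these Hox genes was found in 1 control and 3 cKO libraries at E15, in 1 control and 2 cKO libraries at P7 and in 2 control and 1 cKO library at W8. Hoxa5 at E15 was therefore 54.8 ± 47.3 CPM in control and 0.196 ± 0.339 CPM in cKO brains. Ttr, the abundant transcript of the choroid plexus, ranged from 414 to 1891 CPM at E15, from 8.08 to 1432 CPM at P7 and from 5.77 to 3770 CPM at W8. All 18 libraries are labelled male, yet Xist, the RNA of the inactive X chromosome, lay between 90.8 and 833 CPM, and the sum of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y reached at most 0.0961 CPM. At E15 Xist was at 232 ± 71 CPM in control and 122 ± 32 CPM in cKO brains, with the 3 cKO libraries below the 3 controls (−0.81 ± 0.24, adjusted p = 0.711), and at P7 and W8 the groups overlapped.

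**Figure D1:**
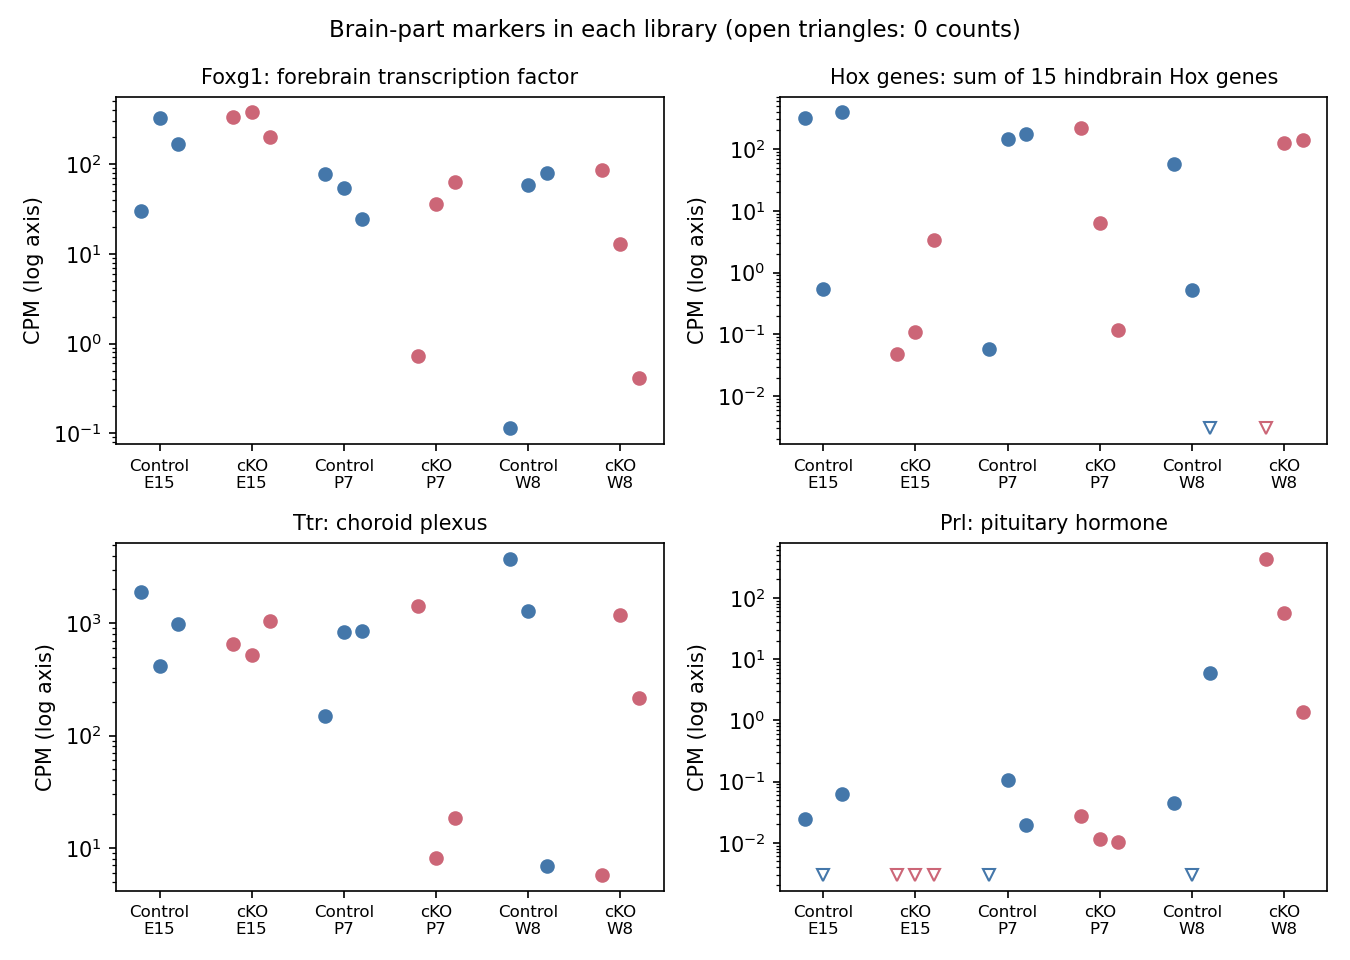
Level of Foxg1, summed Hox genes, Ttr and Prl in each of the 18 libraries, in CPM on a log axis, with 3 control and 3 cKO libraries per stage (points; open triangles mark 0 counts). Foxg1 ranged from 30.2 to 378 CPM between libraries of E15, where the 3 cKO libraries and 1 control library had under 10 CPM of Hox genes.

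Rest (ENSMUSG00000029249) was detected in all 18 brain libraries at similar levels in both genotypes. It averaged 26.0 ± 6.2 CPM in control and 28.2 ± 6.3 CPM in cKO at E15, 11.9 ± 3.7 and 14.3 ± 2.5 CPM at P7, and 10.98 ± 3.997 and 13.3 ± 4.5 CPM at W8 (SD, n = 3). The log2 fold changes were 0.22 ± 0.20, 0.19 ± 0.23 and 0.27 ± 0.35 (SE), and the exact two-sided permutation tests gave p = 0.4, 0.5 and 0.5. A deletion in the placenta need not appear in the brain, so these values do not check the genotype labels.

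At E15 the 10 genes with the smallest p among those meeting the naming criteria, a symbol other than those of predicted, RIKEN, ribosomal protein or histone genes and a mean of at least 1 CPM in some group, were 6 with lower and 4 with higher levels in cKO brains, and none passed the threshold. Lower values were found for Ccser1 (50.2 ± 4.8 CPM in control, 23.9 ± 1.4 in cKO, log2 fold change −0.99 ± 0.15) and for Cntn6, a neuronal adhesion molecule of the contactin family (17.5 ± 3.6 and 9.48 ± 1.29 CPM, −0.78 ± 0.16). Scand1 was lower (20.5 ± 0.3 and 9.37 ± 3.01 CPM, −1.05 ± 0.22), as was Olig3, a transcription factor of dorsal hindbrain and spinal cord progenitors (2.68 ± 0.64 and 1.08 ± 0.21 CPM, −1.20 ± 0.25). Uba52 (−1.08 ± 0.25) and Xlr3b (−1.23 ± 0.29) were also lower, but both have close paralogs or pseudogenes and their counts are uncertain. Higher values were found for Ror2, a receptor of WNT5A (7.35 ± 1.24 and 12.5 ± 1.0 CPM, 0.85 ± 0.19), and for the fibrillar collagen gene Col11a1 (19.5 ± 0.9 and 28.2 ± 3.5 CPM, 0.61 ± 0.14). Csf1r, the growth factor receptor of microglia, was higher (22.8 ± 2.7 and 31.6 ± 3.9 CPM, 0.56 ± 0.13), as was Eps8l1 (2.77 ± 0.86 and 7.81 ± 4.14 CPM, 1.60 ± 0.38). In edgeR's quasi-likelihood test 0 of 21019 genes passed, each of these 10 having an adjusted p of 0.711. At E15 974 genes had an unadjusted p under 0.05 against 1051 expected by chance. limma-voom called 0 genes and DESeq2 called 12, among them Eps8l1, Snca, Cntn6, Hoxb4, Ccser1, Olig3, Scand1 and Uba52. Without control library 2, the control with few Hox reads, 7 genes passed, Hoxb4 and Hoxd4 among them. Without control library 3 a predicted gene, Gm6166, passed. In the 4 libraries with under 10 CPM of Hox genes 3 genes passed, Gm6166, Hmga1b and BC002163, but these are 1 control and 3 cKO libraries and the fit assumes that the lone control varies like the cKO libraries.

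Gene lists at E15 shifted in 9 of 42 cases with the preset correlation and in 0 with a correlation estimated from the data. With the estimated correlation the adjusted p was 0.911 for the nuclear-encoded respiratory chain and 0.843 for each of the other 8 lists, so the calls below hold only with the preset one. Proliferation genes lay higher in cKO brains, with 24 of 24 measured members above 0 (adjusted p = 3.99e-06), for example Mcm4, part of the replicative helicase, at 53.1 CPM in control and 70.8 CPM in cKO (0.49 ± 0.25). Immature neuron genes lay higher with 12 of 14 members above 0 (adjusted p = 0.0210), Neurod1 at 53.5 and 69.2 CPM (0.45 ± 0.18) among them, whereas Stmn2 was at 1426 and 969 CPM (−0.44 ± 0.22). Rest and its corepressors lay higher with 9 of 9 members above 0 (adjusted p = 0.0164), for example Rcor1 at 41.1 and 51.3 CPM (0.39 ± 0.24) and Rcor2 at 113 and 147 CPM (0.45 ± 0.34). These 3 calls were lost with a covariate for brain-part composition, chosen after seeing the data. With it the 3 lists turned downward (camera, adjusted p = 0.513, 0.596 and 0.925 in this order). The Hox genes were below 10 CPM in each cKO brain and at 318 and 392 CPM in 2 of the 3 controls. Microglia genes (13 of 15 above 0, adjusted p = 0.0105) and genes of meninges and fibroblasts (17 of 19, adjusted p = 0.00855) also lay higher. So did red blood cell genes (11 of 13, adjusted p = 0.0118) and placental trophoblast genes (8 of 10, adjusted p = 0.00720), and these 4 calls were kept with that covariate. Examples are Cx3cr1, the fractalkine receptor of microglia (13.4 and 16.0 CPM, 0.35 ± 0.13), the collagen gene Col1a1 (58.7 and 126 CPM, 1.18 ± 0.41) and Alas2, the erythroid enzyme of heme synthesis (32.3 and 46.8 CPM, 0.64 ± 0.17). The trophoblast transcripts were near the floor: Tpbpa, a marker of the spongiotrophoblast, averaged 0.202 ± 0.305 CPM in control and 1.22 ± 0.96 CPM in cKO, and Prl8a9 0.0498 and 0.351 CPM (2.86 ± 1.11). Members of these lists past the threshold numbered 0 over all genes tested and 0 adjusted over the list alone, at E15 as at P7 and W8. With each library left out in turn, the proliferation call was kept in 6 of 6 fits. The calls of Rest and its corepressors and of immature neurons were lost without control library 1 or cKO library 2. Those of microglia were lost without control library 2 or 3, of meninges without control library 2 or 3 or cKO library 3, of red blood cells without control library 2 or cKO library 3, and of trophoblast without control library 2.

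Genes of energy metabolism, the theme in the title of the series, were examined at each stage. Nuclear-encoded respiratory chain genes lay lower in cKO brains at E15 with 31 of 33 members below 0 (adjusted p = 0.0448), for example Cox5a at 98.8 CPM in control and 74.4 CPM in cKO (−0.30 ± 0.14). That adjusted p was 0.911 with an estimated correlation, and with the composition covariate the list turned upward (adjusted p = 0.512). The call was lost without control library 1 or cKO library 1 or 3, and the list did not pass at P7 (adjusted p = 0.709) or W8 (adjusted p = 0.818). Mitochondrially encoded genes lay lower at E15 (8 of 8 members, adjusted p = 0.0131) and W8 (8 of 8, adjusted p = 0.0213), and 8 of 8 lay below 0 at P7 without passing (adjusted p = 0.144). With an estimated correlation the adjusted p of the mitochondrially encoded list was 0.843 at E15 and 0.832 at W8, and with the composition covariate it was 0.612 and 0.0807. Among them mt-Nd5 was at 832 and 585 CPM at E15 (−0.41 ± 0.20), and mt-Nd1 at 6228 and 5045 CPM at W8 (−0.30 ± 0.32). Mitochondrially encoded reads made up 1.13% and 1.22% of the E15 libraries with many Hox reads against 0.747% to 0.865% of the other 4. At W8 they made up 2.75% to 3.05% of the libraries with many Hox reads against 4.58% to 5.75% of those with few, which were 2 control and 1 cKO. The E15 call was lost without control library 3 or cKO library 2, and the W8 call without control library 2 or 3 or cKO library 2 or 3. With the replicate number as a block, and with no filter on low counts, this W8 call was also lost. So was the E15 call of the nuclear-encoded respiratory chain under either alternative. Glycolysis and lactate genes did not pass at E15, P7 or W8 (adjusted p = 0.977, 0.887 and 0.155). Nor did genes of the TCA cycle (adjusted p = 0.757, 0.797 and 0.437), of glutamate, glutamine and GABA metabolism (adjusted p = 0.317, 0.918 and 0.818) or of creatine and N-acetylaspartate metabolism (adjusted p = 0.903, 0.988 and 0.108). The sign of the median differed from that of the test for the creatine list at E15 and P7 and for the glutamate list at P7. The differences between stages in these lists were not tested.

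At P7 the genes with the smallest p among those meeting the naming criteria included Zfp457, a zinc-finger gene with close paralogs and so uncertain counts (0.276 ± 0.019 CPM in control, 1.11 ± 0.03 in cKO, log2 fold change 1.92 ± 0.24), and Myoc, the secreted protein myocilin (2.47 ± 1.66 and 14.5 ± 2.9 CPM, 2.49 ± 0.47). Dera, an aldolase of deoxyribose phosphate, was at 8.72 ± 0.94 and 18.4 ± 4.9 CPM (0.98 ± 0.21), and the immediate early gene Ier2 at 10.4 ± 1.3 and 15.9 ± 1.5 CPM (0.54 ± 0.17). Lower values were found for Ccser1 (16.4 ± 3.3 and 8.81 ± 1.33 CPM, −0.98 ± 0.20), Mmrn1 (2.14 ± 0.31 and 1.26 ± 0.21 CPM, −0.85 ± 0.23) and Plxnd1, a semaphorin receptor (131 ± 24 and 76.5 ± 14.5 CPM, −0.86 ± 0.25). Wnt7b, a secreted WNT ligand, was lower (47.4 ± 4.7 and 32.4 ± 4.2 CPM, −0.62 ± 0.18), as was Itih2 (6.76 ± 1.06 and 4.32 ± 0.27 CPM, −0.73 ± 0.18). Xlr3b, again uncertain, was at −1.15 ± 0.28. In edgeR's test 0 of 22956 genes passed, with an adjusted p of 1 for each of these. At P7 194 genes had an unadjusted p under 0.05 against 1148 expected. limma-voom called 0 genes and DESeq2 called 8, Myoc, Zfp457, Hoxd8 and Nlrp5-ps among them. In the 3 libraries with under 10 CPM of Hox genes, 38 genes passed, from 1 control library, assumed to vary like the others, and 2 cKO libraries.

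Gene lists at P7 shifted in 6 of 42 cases with the preset correlation and in 0 with an estimated correlation, where each of these 6 lists had an adjusted p of 0.977. Cerebellar genes lay higher in cKO brains with 16 of 16 measured members above 0 (adjusted p = 0.000518), among them Car8 of Purkinje cells (207 and 340 CPM, 0.64 ± 0.40) and Gabra6 of granule cells (10.99 ± 10.15 and 31.1 ± 8.3 CPM, 1.46 ± 1.20). Control library 1 had low levels of the cerebellar genes Gabra6, at 0.158 CPM against 12.5 and 20.3 CPM in the other controls, and Pcp2, at 0.222 CPM against 25.4 and 35.2 CPM. Without that library the cerebellar call was lost. Proliferation genes lay higher with 24 of 24 members above 0 (adjusted p = 0.0122), Cdk1 at 22.9 and 34.7 CPM (0.51 ± 0.39) being an example, and hypothalamic genes with 14 of 16 (adjusted p = 0.0466). The hypothalamic shift was led by neuropeptide genes of low level, Pmch at 0.0647 and 2.58 CPM (5.22 ± 1.84), Oxt at 0.0402 and 1.53 CPM (5.14 ± 1.90) and Hcrt at 0.106 and 1.13 CPM (3.31 ± 1.39), and the call was lost with the composition covariate (adjusted p = 0.0582). Glutamatergic neuron genes lay lower with 15 of 16 members below 0 (adjusted p = 0.00104), for example Cux2, a transcription factor of upper cortical layers (82.9 and 64.2 CPM, −0.46 ± 0.21). Genes of meninges and fibroblasts (18 of 19 below 0, adjusted p = 0.00100; Dcn at 51.5 and 37.4 CPM, −0.54 ± 0.17) and of choroid plexus (16 of 20, adjusted p = 0.00810; Kcne2 at 5.81 and 2.56 CPM, −1.31 ± 1.33) also lay lower. Ttr was at 149, 829 and 861 CPM in the control libraries and at 1432, 8.08 and 18.3 CPM in the cKO libraries. Foxg1 at this stage was 52.0 ± 26.7 CPM in control and 33.4 ± 31.5 CPM in cKO brains. The proliferation call was lost without control library 1 or cKO library 1 or 2, the hypothalamic call without control library 1 or cKO library 2, and the glutamatergic call without control library 2 or cKO library 1. The meningeal call was lost without control library 2, and that of choroid plexus without control library 2 or 3 or cKO library 2 or 3.

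At W8 the genes with the smallest p among those meeting the naming criteria included AA465934 (0.903 ± 0.431 CPM in control, 6.42 ± 0.19 in cKO, log2 fold change 2.83 ± 0.44) and Pkdrej (0.614 ± 0.022 and 1.62 ± 0.34 CPM, 1.41 ± 0.39) with higher values in cKO brains. Lower values were found for Aqp1, the water channel of the choroid plexus (13.9 ± 11.6 and 2.25 ± 1.51 CPM, −2.62 ± 0.72), and Nlrc5, a transactivator of MHC class I genes (1.22 ± 0.25 and 0.325 ± 0.033 CPM, −1.89 ± 0.43). Mdfic (11.4 ± 4.4 and 4.62 ± 1.03 CPM, −1.28 ± 0.35) and Zfp131 (58.3 ± 10.7 and 31.7 ± 3.4 CPM, −0.89 ± 0.18) were also lower. So were Esco1, an acetyltransferase of cohesin (30.6 ± 3.9 and 20.9 ± 1.7 CPM, −0.56 ± 0.16) and Adi1, an enzyme of methionine salvage (77.4 ± 11.7 and 52.1 ± 3.9 CPM, −0.56 ± 0.16). Rd3 (1.90 ± 0.89 and 0.491 ± 0.089 CPM) and Cox7b2 (1.16 ± 0.48 and 0.305 ± 0.053 CPM) were at −1.94 ± 0.46 and −1.91 ± 0.49. In edgeR's test 0 of 18186 genes passed, with an adjusted p of 1 for each of these. At W8 140 genes had an unadjusted p under 0.05 against 909 expected. limma-voom called 0 genes and DESeq2 called 2, AA465934 and the predicted gene Gm45104. With 1 surrogate variable, added after seeing the data, Hoxb6 passed.

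Gene lists at W8 shifted in 6 of 42 cases with the preset correlation and in 0 with an estimated correlation. In the latter camera test the adjusted p was 0.671 for the pituitary list and 0.832 for the other 5. The estimated correlation was −0.13 for the pituitary list and −0.04 for oligodendrocyte precursors, below the preset 0.01. It was 0.25 to 0.93 for the rest of the called lists. Correlation between members therefore does not account for the loss of the pituitary and precursor calls. Choroid plexus genes lay lower in cKO brains with 20 of 20 measured members below 0 (adjusted p = 5.93e-05), Tmem72 at 18.7 and 2.09 CPM (−3.15 ± 1.26) and Clic6 at 36.7 and 15.3 CPM (−1.23 ± 0.69) beside Aqp1. Libraries of both genotypes stood apart in this tissue: Ttr was at 3770, 1275 and 6.96 CPM in control libraries 1, 2 and 3 and at 5.77, 1180 and 218 CPM in cKO libraries 1, 2 and 3. The mean log2 CPM of the list overlapped, from 0.29 to 5.19 in control and from 0.15 to 3.21 in cKO, and the call was lost without control library 1 or cKO library 1. Myelin genes lay higher with 16 of 16 members above 0 (adjusted p = 0.00137), for example Trf, transferrin (452 and 832 CPM, 0.87 ± 0.54), and Mog (126 and 187 CPM, 0.56 ± 0.44). Oligodendrocyte precursor genes lay higher with 10 of 11 (adjusted p = 0.0405), Olig2 at 44.3 and 57.1 CPM (0.36 ± 0.19), a call kept in 0 of 6 fits with a library left out. Imprinted genes lay higher with 23 of 29 (adjusted p = 0.0178), led by Dlk1 at 28.7 and 59.8 CPM (1.07 ± 0.39), while Igf2 was at 3.41 and 2.36 CPM (−0.53 ± 0.26), and the call was lost with the composition covariate (adjusted p = 0.0959). Pituitary genes lay higher with 7 of 7 (adjusted p = 0.00137) and kept the call in 6 of 6 such fits. The pituitary hormone gene Prl was at 439 CPM (interval 434 to 445) in cKO library 1, at 56.9 CPM in library 2 and at 1.35 CPM in library 3, and reached at most 5.99 CPM in control brains. Gh ran from 0.433 to 188 CPM in cKO brains and reached at most 5.52 CPM in controls. By fry, which does not compare a list with other genes, the unadjusted p was 0.00592 for the pituitary list and 0.0127 for oligodendrocyte precursors, the only 2 under 0.05 among 42 lists at W8 and 126 tests over the stages. The imprinted call was lost without control library 3 or cKO library 3, and the myelin call without control library 3 or cKO library 2.

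Neuronal genes with a textbook REST binding element, the class most directly tied to the knocked-out repressor, did not pass at any of the 3 stages. Of its 25 measured members 19 lay below 0 at E15 (median log2 fold change −0.25, adjusted p = 0.112), 21 lay below 0 at P7 (median −0.13, adjusted p = 0.258) and 19 lay above 0 at W8 (median 0.09, adjusted p = 0.243), by camera with the preset correlation. The difference between stages was not tested.

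Across the 3 stages Ccser1 (ENSMUSG00000039578), a gene for a coiled-coil serine-rich protein, was the only gene of 24624 to pass the common genotype term of edgeR. It was lower in cKO brains by 0.98 ± 0.13 on the log2 scale (−0.98, ratio 0.509, adjusted p = 0.0128). The 3 cKO libraries lay below the 3 controls at each stage: 50.2 ± 4.8 and 23.9 ± 1.4 CPM at E15, 16.4 ± 3.3 and 8.81 ± 1.33 CPM at P7, 16.0 ± 6.6 and 8.05 ± 0.71 CPM at W8. The antisense neighbour A730020E08Rik, named after its values were seen, was at 9.45 ± 1.58 and 4.74 ± 0.57 CPM at E15 and similarly lower later (−1.07 ± 0.18 over the stages, adjusted p = 0.117). Its start overlaps that of Ccser1 on the opposite strand, and without a stated strand setting reads from the shared stretch cannot be told apart. How far the counts of the 2 genes share reads was not examined. Of 17615 genes tested at every stage, these 2 had non-overlapping groups in the same direction at all 3, where chance gives 4.40. Among genes meeting the naming criteria, the next smallest p belonged to Ddx4, a germ-line RNA helicase (−1.02 ± 0.23), Xlr3b (−1.09 ± 0.25), Ccl28 (−0.98 ± 0.25), Nlrp5-ps, a pseudogene with uncertain counts (−1.24 ± 0.33), and Snca, which encodes alpha-synuclein (−1.45 ± 0.41), each with an adjusted p of 1.00. Rest was at 0.24 ± 0.15. DESeq2 called 4 genes, Ccser1, Ddx4, Xlr3b and A730020E08Rik, and limma-voom called Ccser1 and A730020E08Rik. An unadjusted p under 0.05 was found for 316 genes against 1231 expected. The call of Ccser1 did not survive leaving out any of 10 of the 18 libraries. They were control libraries 2 and 3 and cKO library 3 of E15, the same numbers of P7, and control libraries 1 and 2 and cKO libraries 1 and 3 of W8. Without each of them the log2 fold change lay between −0.97 and −0.89 and the adjusted p between 0.0536 and 0.105. The call was also lost with the replicate number as a block (0 genes, adjusted p = 0.196) and in the 4 control and 6 cKO libraries with under 10 CPM of Hox genes (0 genes, adjusted p = 0.999). In those libraries the log2 fold change of Ccser1, given with the dependence on processing, stayed close to the main one. With the composition covariate 3 genes were called, Ccser1, A730020E08Rik and Snca.

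**Figure D2:**
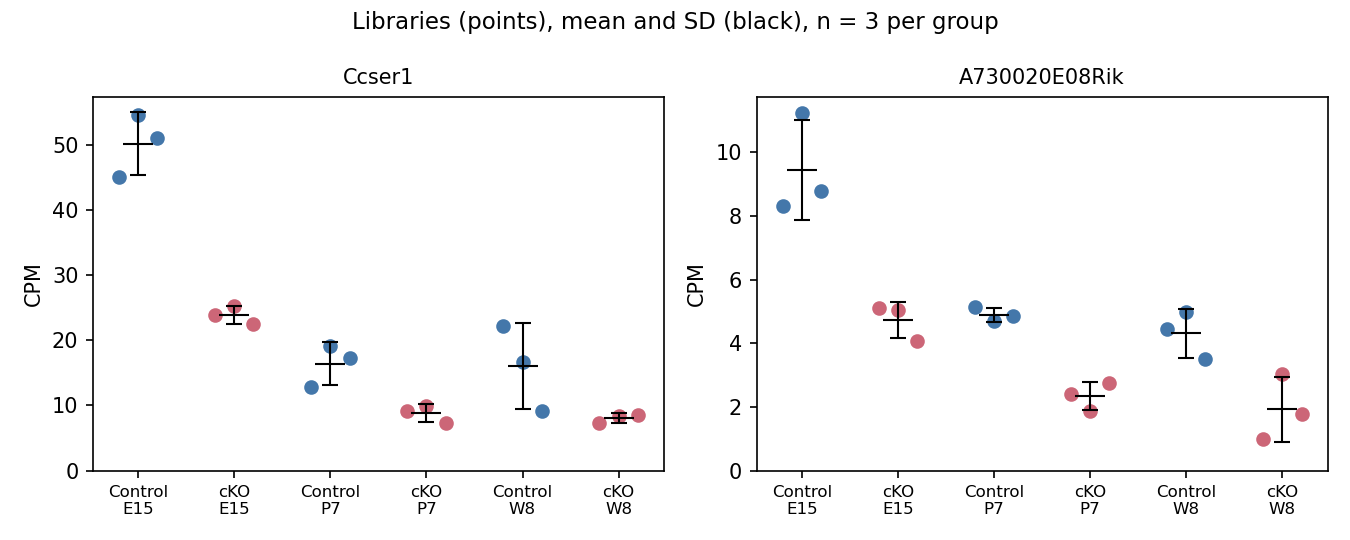
Level of Ccser1 and A730020E08Rik in each library, in CPM on linear axes, by stage and genotype (points are libraries; bars give mean ± SD of 3). The 3 cKO libraries lie below the 3 control libraries at each stage for both genes, for example at 23.9 ± 1.4 against 50.2 ± 4.8 CPM for Ccser1 at E15.

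The neighbours of Ccser1 on the side of A730020E08Rik had log2 fold changes below 0 over the stages. In chromosome order these were A730020E08Rik, Mmrn1 (−0.61 ± 0.33, adjusted p = 1.00) and Snca. The next expressed gene beyond Snca, Gprin3, was at −0.11 ± 0.21. On the other side of Ccser1, 9330118I20Rik and Grid2 were at −0.40 ± 0.32 and −0.15 ± 0.47. Further on that side Gm44075, with few reads, was at −1.28 ± 0.80 and Atoh1 at −0.52 ± 1.12. The errors of 9330118I20Rik and Mmrn1 overlap, so the edge of the low run on that side is not sharp. Snca was at 104.6 ± 62.4 and 29.3 ± 8.6 CPM at E15, 412 ± 253 and 169 ± 110 CPM at P7, and 160 ± 103 and 63.8 ± 54.3 CPM at W8 in control and cKO brains, and its groups overlapped at P7 and W8. Those of Mmrn1 overlapped at E15, and at W8, where it was not tested, it had 2 reads in 1 control library, 2 in 1 cKO library and 0 in the others.

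**Figure D3:**
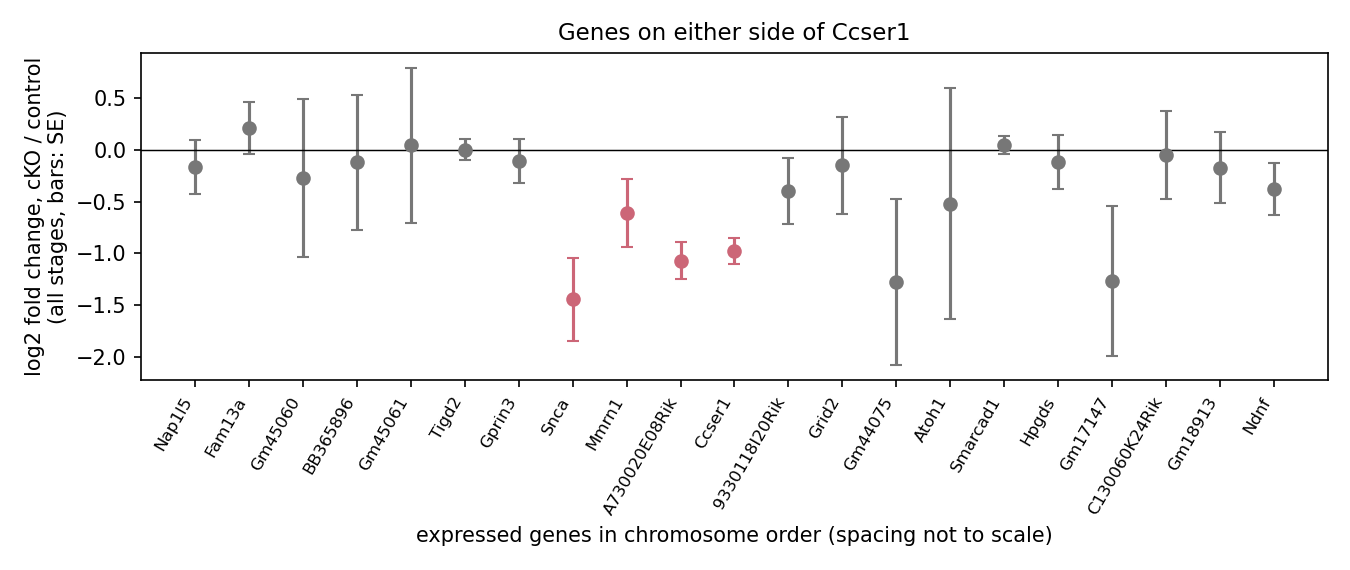
Log2 fold change of cKO over control across all stages for the 21 expressed genes around Ccser1 in chromosome order (points; bars give ± 1 SE; spacing is not to scale). Snca, Mmrn1, A730020E08Rik and Ccser1 lie between −1.45 and −0.61. The genes next to this run on either side, Gprin3 and 9330118I20Rik, lie at −0.11 ± 0.21 and −0.40 ± 0.32. Gm44075 and Gm17147, with few reads, lie at −1.28 ± 0.80 and −1.27 ± 0.72.

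Whether the genotype effect differs between stages was tested with the interaction term. Among genes meeting the naming criteria, the smallest p belonged to Scand1, which was lower in cKO brains at E15 and higher at P7 (20.5 ± 0.3 and 9.37 ± 3.01 CPM, then 12.3 ± 3.5 and 18.1 ± 1.6 CPM). Next under these criteria were Tma7-ps, a pseudogene with uncertain counts, and Slc7a11, the cystine transporter (17.0 ± 8.5 and 141 ± 100 CPM at E15, 55.2 ± 6.5 and 51.8 ± 11.3 CPM at P7). The E15 mean of Slc7a11 rested on cKO libraries 2 and 3, at 201 and 197 CPM, since library 1 was at 25.9 CPM. Abcg5, Ankle1 and Tuba1c completed the 6. Tuba1c, an alpha-tubulin gene with close paralogs, was at 9.35 ± 0.75 and 27.8 ± 15.5 CPM at E15 and at 1.81 ± 1.06 and 0.576 ± 0.223 CPM at W8. In edgeR's test 0 of 24624 genes passed, with an adjusted p of 1 for each of these 6. There were 776 genes that had an unadjusted p under 0.05 against 1231 expected. limma-voom called 0 genes and DESeq2 called 19. Without control library 3 of W8, where Tma7-ps was at 0.133 CPM against 7.04 and 4.22 CPM in the other controls, edgeR called Tma7-ps and Trim12a. With the composition covariate it called Neu4 and Hoxb7.

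No gene passed the threshold in any pair of stages, so 0 calls were shared where 0 were expected. At an unadjusted p under 0.05, 9 genes were lower in cKO brains at both E15 and P7 against 2.72 expected (one-sided Fisher's exact test, adjusted p = 0.0122 over the 12 overlaps tested), Ccser1, A730020E08Rik, Xlr3b, Ddx4 and Ccl28 among them. At both P7 and W8, Ccser1, A730020E08Rik and the histone gene Hist1h1c were lower, 3 against 0.251 expected (adjusted p = 0.0122), and AA465934 and Xaf1 were higher, 2 against 0.161 expected (adjusted p = 0.0453). Fisher's test takes genes as independent. Ccser1 and A730020E08Rik may share reads and be a single signal, but count separately in both of these overlaps of lower genes. These p therefore cannot be taken at face value. The other overlaps at that p did not pass: 2 genes higher at E15 and P7 against 0.795 expected (adjusted p = 0.566), and at E15 and W8 3 lower against 2.43 and 1 higher against 0.698 (adjusted p = 1 for both). Log2 fold changes correlated across genes at r = −0.02 between E15 and P7, 0.03 between P7 and W8 and −0.13 between E15 and W8, and genes are not independent replicates.

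Control brains changed broadly between E15 and P7. Many genes of the glial and glutamatergic neuron lists rose, and many of the progenitor and red blood cell lists fell. Members were counted here, and no list was tested as a set. Astrocyte genes rose in 11 of 14 cases (12 adjusted over the list alone, where 1 fell), led by Gfap, the astrocyte filament protein (5.79 ± 8.00 to 489 ± 198 CPM, log2 fold change 6.44 ± 1.17), and Agt (1.11 ± 1.00 to 53.5 ± 40.6 CPM, 5.60 ± 1.10). Oligodendrocyte precursor genes rose in 9 of 11 (10 over the list alone, where 1 fell) and myelin genes in 9 of 15 (14 over the list alone), for example Plp1 (5.48 ± 1.26) and Mbp (5.03 ± 1.10). Microglia genes rose in 10 of 15 (15 over the list alone), for example P2ry12 (1.79 ± 0.21). Glutamatergic neuron genes rose in 8 of 16 (9 over the list alone), led by Nrgn, the postsynaptic protein neurogranin (13.6 ± 2.6 to 658 ± 508 CPM, 5.60 ± 0.67). Of 17 GABAergic neuron genes 1 rose and 2 fell (1 and 3 over the list alone). Of 25 neuronal genes with a REST element 10 rose (15 over the list alone, where 1 fell), Snap25 by 1.97 ± 0.32 among them. Of the 9 genes in the list of Rest and its corepressors 5 fell (6 over the list alone), Rest itself (−1.16 ± 0.24, adjusted p = 0.0202) and Hdac2 (−1.25 ± 0.20) among them. Circadian clock genes rose in 12 of 15 and fell in 1 (12 and 1 over the list alone) and mitochondrially encoded genes in 7 of 8 (7 over the list alone). Red blood cell genes fell in 12 of 13 (12 over the list alone), the embryonic globins Hbb-y (13.99 ± 3.81 to 0.0472 ± 0.0246 CPM, −8.20 ± 0.48) and Hba-x (−7.79 ± 0.92) most, though globin paralogs can share reads. Neural progenitor genes fell in 7 of 15 and rose in 1 (9 and 1 over the list alone), for example Neurog2 (−5.00 ± 0.71). The regional transcription factors Lhx8 (15.0 ± 10.95 to 0.0904 ± 0.0254 CPM), Nkx2-1 (22.8 ± 16.9 to 0.586 ± 0.150 CPM) and Isl1 (34.0 ± 11.4 to 1.11 ± 0.48 CPM) fell by 7.45 ± 0.94, 5.38 ± 0.88 and 5.01 ± 0.48 on the log2 scale. Gabra6 (6.59 ± 1.79) and Tmem212 of ependymal cells (5.53 ± 1.25) rose. In edgeR's test 2700 genes rose and 1827 fell of 22350 (DESeq2 called 6812 and limma-voom 4424). The count fell to 1358 or 816 without control library 2 or 3 of E15, and to 1676 or 1452 without control library 2 or 3 of P7.

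Between P7 and W8 most genes of the proliferation list fell in control brains, and part of the clock, interferon and glycolysis lists rose. Again members were counted and no list was tested as a set. Proliferation genes fell in 22 of 24 cases (24 adjusted over the list alone), Mki67 from 78.2 ± 52.7 to 1.19 ± 0.38 CPM (−5.88 ± 0.75) and Aurkb, a mitotic kinase, from 11.3 ± 5.6 to 0.209 ± 0.134 CPM (−5.60 ± 0.66). Cholesterol synthesis genes fell in 10 of 18 (10 over the list alone), for example Hmgcr, the rate-limiting enzyme (−1.49 ± 0.29). Immature neuron genes fell in 5 of 14 (9 over the list alone), Nhlh1 from 21.5 ± 18.1 to 0.435 ± 0.185 CPM (−5.45 ± 1.32). The imprinted RNA H19 fell from 28.8 ± 6.9 to 0.566 ± 0.388 CPM (−5.56 ± 0.62). Glycolysis and lactate genes rose in 13 of 23 and fell in 2 (14 and 3 over the list alone), with Aldoc, the brain aldolase, at 1.84 ± 0.29. Circadian clock genes rose in 9 of 15 (12 over the list alone), Dbp by 2.95 ± 0.22. Interferon response genes rose in 7 of 18 (12 over the list alone), Ifit3b from 0.406 ± 0.044 to 5.82 ± 1.03 CPM (3.96 ± 0.35). Ly6a of endothelium rose from 1.66 ± 0.12 to 21.7 ± 0.8 CPM (3.82 ± 0.22), and the activity-regulated gene Arc from 8.89 ± 2.53 to 95.4 ± 52.2 CPM (3.57 ± 0.54). The myelin gene Hapln2 rose from 2.77 ± 2.36 to 30.9 ± 22.7 CPM (3.62 ± 0.91) and Oxt, oxytocin, from 0.0402 ± 0.0202 to 13.5 ± 13.9 CPM (8.49 ± 1.80). The lens gene Crygs went from 0.179 ± 0.011 CPM to 0 reads in the 3 adult libraries. In edgeR's test 1272 genes rose and 1253 fell of 20568 (DESeq2 called 4560 and limma-voom 2331). The count fell to 501 or 446 without control library 2 or 3 of P7, and to 665 or 1227 without control library 2 or 3 of W8. It was 179 with the replicate number as a block, 4519 with the composition covariate and 4316 with 1 surrogate variable.

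**Figure D4:**
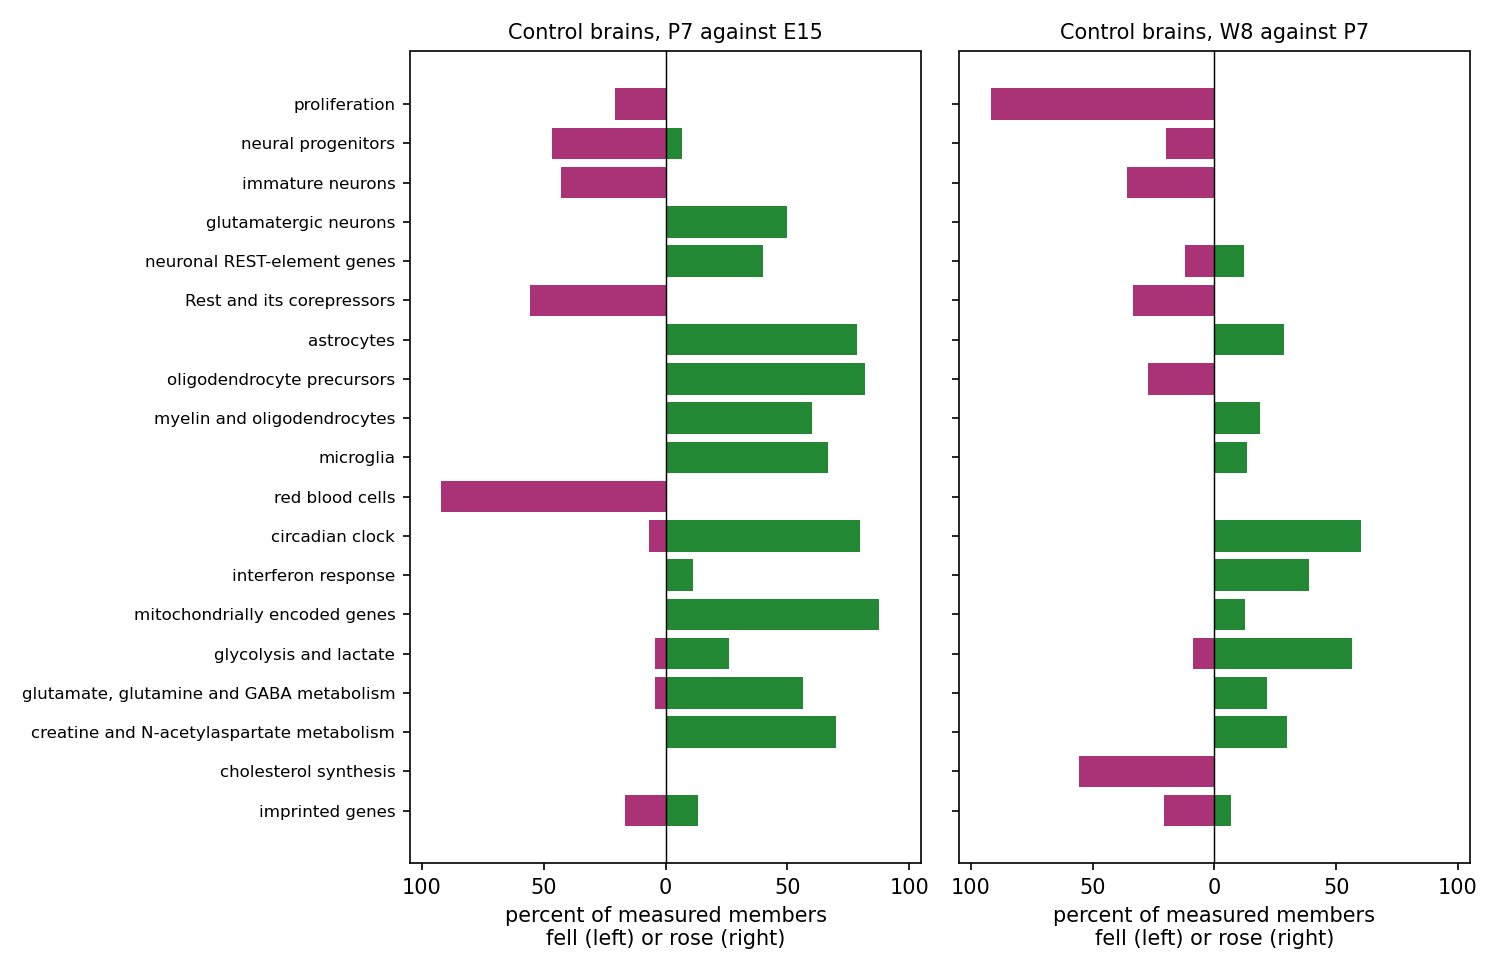
Percent of the measured members of gene lists that rose (right) or fell (left) past an adjusted p of 0.05 in edgeR between control brains of successive stages, 3 libraries each. Between E15 and P7, 11 of 14 astrocyte genes rose and 12 of 13 red blood cell genes fell, and between P7 and W8, 22 of 24 proliferation genes fell.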

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

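The tests of the Foxg1 ratio, of Hox genes in control libraries, of the neighbours of Ccser1, of its sign at the 3 stages and of Xist and the Y-linked genes were chosen after the results were seen, and the fits with a composition covariate were added after the data were seen.

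For 3 of 59 named genes the 3 cKO libraries lay beyond the 3 controls in opposite directions at different stages, and for none did a test of the difference pass over all genes (adjusted p = 1 for each). Scand1 was lower at E15 and higher at P7 (unadjusted p of edgeR's interaction 0.000249). Adi1 was higher at E15 (21.2 ± 0.8 CPM in control, 25.7 ± 1.1 in cKO) and lower at W8 (unadjusted p of edgeR's interaction 0.00247). Pkdrej was lower at P7 (0.557 ± 0.0005 and 0.436 ± 0.031 CPM) and higher at W8 (unadjusted p of edgeR's interaction 0.00989). These genes had been named for a small p at a stage or, for Scand1, also in the interaction, and adjusted over the 39 named genes tested the p was 0.00677, 0.0128 and 0.0351, which is no independent evidence. In all, 146 of 17615 genes met the same criterion where chance gives 251.

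Libraries labelled whole brain differed in Foxg1 by 12.5 times or more within each stage, and in Hox genes from under 0.1 to over 100 CPM. The cKO genotype as the cause is argued against by 4 control libraries with under 10 CPM of Hox genes. Different parts of the brain in the samples are a candidate explanation, but its bounds were set after the values were seen and replaced an earlier test, so the ratio of 12.5 is not a test passed. With a covariate for this axis, in a test set before its result was seen, 13 of the 21 list calls between genotypes were kept, which lies between the bounds set for and against brain parts as their source. At E15, where 4 of 9 calls were kept, brain parts and genotype cannot be told apart because the 3 cKO libraries were among the 4 with few Hox reads, while at P7 and W8 both genotypes held both kinds and 5 of 6 and 4 of 6 were kept, cerebellum and choroid plexus among them, tissues that the covariate was not built to measure.

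Ccser1 and A730020E08Rik were lower in cKO brains at all stages, with non-overlapping groups. Snca, further along, overlapped between genotypes at P7 and W8, and Mmrn1 overlapped at E15 and was almost unread at W8. With the composition covariate the common term of edgeR put Snca at −1.01 ± 0.14 (adjusted p = 0.0255), against −1.45 ± 0.41 without it. Mmrn1 was at −0.548 ± 0.265 with the covariate and did not pass. The axis of Hox and forebrain genes as the whole cause is argued against for Ccser1, since with it as a covariate its log2 fold change was −1.05 ± 0.12 (adjusted p = 0.00272) against −0.98 ± 0.13 without it, with adjusted p of 2.17e-08 to 0.999 over all its alternatives. A sequence difference at the locus in the cKO animals may account for it and stays open: the mean of Snca, Mmrn1 and A730020E08Rik, −1.04, was as low in 50 of 24427 runs of 3 neighbouring expressed genes (0.205%), but these genes were looked at because they were low and A730020E08Rik may share reads with Ccser1, so this share does not support it. Snca was still read in each cKO library, at 21.5 CPM or more, so it was not wholly missing from these brains. Such reads cannot tell whether a single copy was lost, and counts per gene hold no sequence to test further. A lasting response to loss of placental REST cannot be told apart from it, as the largest of the 3 stage log2 fold changes, −0.98, has the sign that both predict.

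All 18 libraries carry the label male. Loss of Y-linked reads in mapping or counting is argued against by Xist, which male cells silence and which was at 90.8 CPM or more in every library. The sum of Ddx3y, Kdm5d, Uty and Eif2s3y was at most 0.0961 CPM in every library, as tissue from females would give. Together these values argue against the label male for the tissue sequenced in all 18 libraries. No biological explanation was tested.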

How the results depend on the processing

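The composition covariate, the fits of libraries with few Hox reads and the surrogate variable were added after the data were seen. Of the named genes, 907 values under the alternatives set in advance kept their direction and side of the threshold, 16 gained a call and 61 lost one. Under the added ones 179, 3 and 5 did so. At E15, P7 and W8 no named gene passed in the main fit, so there a kept side means a value that stayed uncalled. Over both kinds of alternative these made up 214, 200 and 219 of the unchanged values, which are no evidence for the effects. Of the counts and Rest, 154 stayed within 1.5 times or on their side and 38 moved under those set in advance, and 23 stayed, 11 moved and 1 reversed under the added ones. The causes of the changes below were not tested.

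DESeq2 called 12 genes at E15, 8 at P7, 2 at W8, 19 for the interaction, 4 for the common term, 6812 between control E15 and P7 and 4560 between P7 and W8. limma-voom called 2 for the common term. With the replicate number as a block, which the numbers do not support as a pairing (r = −0.595 to 0.368 over 9 pairs, 3 over 0.1), the common term gave 0 genes and Ccser1 lost its call (adjusted p = 0.196). Under that block control W8 against P7 gave 179. With only the libraries with few Hox reads there were 3 genes at E15, 38 at P7 and 0 for the common term, with Ccser1 at −0.90 ± 0.19 from 10 libraries, and Rest at W8 reversed to −0.13 (adjusted p = 1). These fits hold 1 control and 3 cKO libraries at E15, 1 and 2 at P7 and 2 and 1 at W8. They assume that a lone library varies like the others, so their calls and the reversal are weak evidence. Control P7 against E15 could not be fitted on those libraries, with 1 against 1. With 1 surrogate variable there was 1 gene at W8, Hoxb6, and 4316 for W8 against P7. With the composition covariate there were 2 genes for the interaction, Neu4 and Hoxb7, 3 for the common term, Ccser1, A730020E08Rik and Snca, and 4519 for W8 against P7.

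Gene lists past the threshold fell to 0 at each of the 3 stages with an estimated correlation. There were 14 at E15 and 10 at W8 with the composition covariate, 11 at P7 with only the libraries with few Hox reads (1 control and 2 cKO) and 3 at W8 with no filter on low counts. With each library left out in turn, the counts of genes ranged from 0 to 7 at E15, from 0 to 2 for the interaction, and from 0 to 2 for the common term. They ranged from 816 to 4939 for P7 against E15 and from 446 to 2117 for W8 against P7. The counts of lists ranged from 7 to 14 at E15, from 7 to 9 at P7 and from 5 to 8 at W8. At E15 the 7 genes came without control library 2, the 14 lists without control library 1 or cKO library 3 and the 7 lists without control library 3 or cKO library 2. Over the genes tested in both fits, the filter of 1 CPM moved log2 fold changes of P7 against E15 by a median of 0.10. No other alternative moved the shared genes of a comparison by a median of over 0.1. With no filter on low counts, the median over all genes tested for W8 against P7 was −0.42 against −0.02. Those 2 medians cover different sets of genes. The W8 libraries held the fewest reads, 44030423 to 60188045, and 0% of simulated changes of 2-fold were recovered there against 4% at P7. The spread between replicates was also larger at W8 (biological coefficient of variation 0.450 against 0.383), and which of these limits the test was not examined.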

Other observations

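Between E15 and P7 the counts of called members differed between the metabolic lists of the control brains, which were not compared by a test. Over all 22350 genes tested, 2700 rose and 1827 fell. TCA cycle genes rose in 4 of 23 cases and fell in 1, and glycolysis and lactate genes rose in 6 of 23 and fell in 1. Of 33 nuclear-encoded respiratory chain genes 0 passed. Genes of creatine and N-acetylaspartate metabolism rose in 7 of 10 cases (7 adjusted over the list alone). Genes of glutamate, glutamine and GABA metabolism rose in 13 of 23 and fell in 1 (15 and 1 over the list alone). Proliferation genes fell in 5 of 24 (17 over the list alone) and immature neuron genes in 6 of 14 (7 over the list alone). Between P7 and W8 these lists fell in 22 of 24 and 5 of 14 cases, not matched gene by gene. Between P7 and W8 imprinted genes fell in 6 of 29 and rose in 2 (7 and 2 over the list alone). Endothelial genes rose in 5 of 13 and fell in 1 (5 and 1 over the list alone), and 0 of 16 glutamatergic neuron genes passed (0 over the list alone).

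Other splits of the libraries were counted by tests set before their results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and where the real count is 0 every split reaches it by construction. At E15 all 10 gave at least the 0 genes of the real split, the highest other giving 335, and 7 gave at least its 9 lists (highest other 18). At P7 all 10 gave at least 0 genes (highest other 15) and 10 at least 6 lists (highest other 16). At W8 all 10 gave at least 0 genes, and 9 at least 6 lists (highest other 14). The highest other for genes, 3219 genes, parted the 3 libraries with few Hox reads from the 3 with many, so these libraries have a structure that does not follow genotype. For control P7 against E15 only the real split, 1 of 10, gave as many as 4527 genes (highest other 6), and for W8 against P7 only the real split, 1 of 10, gave as many as 2525 (highest other 12). Among 100 splits within stages, 100 gave at least the 0 genes of the interaction (highest other 2166), which any split must, so that count says nothing about chance. For the common term 3 of 100 gave at least the 1 gene found, the real split among them, a share under the bound of 0.05 set beforehand. Other splits, which do not follow genotype, gave 925 and 4 genes, more than the real one. A count of 1 therefore does not exclude chance. The count is Ccser1 alone and fragile: it was 0 in 10 of the 18 fits with a library left out and with the replicate number as a block. Fewer genes than chance gives lay apart in the same direction at all 3 stages (2 against 4.40). Fewer also had an unadjusted p under 0.05 in edgeR's test (316 against 1231), and 528 did with the composition covariate. The number of genes with such a p swung widely over the 10 splits within a stage, from 87 to 3608 at P7 and from 140 to 5852 at W8. A count below the 1231 expected therefore does not measure how strict the test was. These counts neither show nor exclude a broad effect.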
